A study of Homo sapiens with 9 samples.

How the data were processed

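Gene expression was measured in MCF7-FR cells, a line derived from the estrogen receptor positive breast cancer line MCF7 and resistant to fulvestrant, a drug that blocks the estrogen receptor and drives its degradation. Per the labels' protocols, cells were grown with fulvestrant in phenol red-free medium with charcoal-stripped serum. Antagomirs, antisense oligonucleotides that block a mature microRNA, were transfected at 100 nM with Lipofectamine. The groups were a control, an antagomir against miR-221 (si221) and an antagomir against miR-222 (si222), with 3 arrays in each of the 3 groups. The series title speaks of a GFP control inhibitor, but the control samples carry no transfection protocol, so whether the controls received an oligonucleotide is not settled here. Total RNA was extracted with Trizol, and biotinylated cRNA was made from 6 ug of it, per the labels' protocols. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so every p-value measures only the spread between these arrays, which may be technical.

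The deposited value table holds log2 signals of 54675 Affymetrix probe sets on 9 arrays, and the submitters' processing notes name MAS5, which summarises each array on its own. On the linear scale the mean of each array's signals, after trimming 2% at each end, was 1000 on every array, so the deposited values are scaled per array and carry no correction across arrays. Log2 values ran from -2.53 to 17.1. Further filters by the authors are not given in the sources used here. No column was left unused. Arrays give no read depth, and their number limits the precision.

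Deposited values were returned to the linear scale and tested as log2(signal + 31), where 31 is the 20th percentile of all signals. Fold changes are on this scale, which understates the change of dim genes. Of the probe sets, 41091 carried 1 gene symbol, 1801 carried several and 11721 carried none in the annotation table used, and 62 were controls of the array. Entrez identifiers were found in a RefSeq gene table for 41037 probe sets, and 0 symbols needed an update. The probe sets in the top 60% by mean over all arrays were kept, without the controls, which left 32747. Each gene was represented by the probe set with a single symbol and the highest mean, which gave 13221 genes. No coordinates are given, because no genome build is named in the sources used here.

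Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) in 1 fit of all 9 arrays with the group as the only term. The fit had 6 residual degrees of freedom and a prior of 1.86. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The comparisons were si221 against control, si222 against control and si222 against si221, with a moderated F test over the 3 groups. The replicate numbers were not used to pair arrays, since correlations of same-numbered deviations between groups lay between -0.017 and 0.03. Tables were prepared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

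A total of 26 gene lists were fixed before the data were examined: reported targets of miR-221 and miR-222, estrogen response, interferon response, G2/M and mitosis, DNA replication and S phase, p53 targets, apoptosis regulators, TGF-beta, WNT, PI3K with AKT and FOXO, ERBB and MAPK, cholesterol synthesis, unfolded protein response, hypoxia and glycolysis, NF-kappaB and inflammation, epithelial, mesenchymal, basal breast and leukocyte markers, ribosomal proteins, oxidative phosphorylation, histones, heat shock, metallothioneins with oxidative stress, microRNA machinery, and fulvestrant and drug handling. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison, with an estimated correlation and fry as alternatives. The target list was compiled from general knowledge of the field.

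Named genes followed a rule fixed at the same time: the 8 largest changes in each direction among called genes whose arrays did not overlap between groups, up to 3 called members in each direction of each list described, otherwise the 2 members with the smallest p, and 10 reported targets whatever their values. Other genes are named as chosen after their values were seen. The response correlation was set beside 100 simulations of unchanged groups against shared controls.

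The limma procedure was tested on simulated data built on these arrays. For si221 against control it recovered 18% of genes changed 1.25-fold, 52% of those changed 1.5-fold, 76% of those changed 2-fold and 96% of those changed 3-fold, with 10 false calls among 13221 genes. Alternatives covered the pseudocount, the filter, between-array normalization, the handling of several probe sets, the variance model, the arrays in the fit, a replicate block and leaving out each array. A planned search for microRNA seed sites was not run, because no 3' UTR sequences were used here.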

Results

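Messenger RNA was profiled on 9 arrays of fulvestrant-resistant MCF7-FR cells, 3 each from the control, si221 and si222 groups. The 2 microRNAs have the same seed, bases 2 to 8 of the mature sequence, and the comparisons ask which transcripts differ when either one is targeted and whether the responses differ from each other. Mature microRNAs are not measured by this array, so their knockdown cannot be checked here. Median signals were 168 ± 1.29 (SD, n = 3) in control, 174 ± 2.6 in si221 and 174 ± 8.07 in si222. Spearman correlations between arrays ran from 0.943 to 0.951 over all probe sets, and no arrays held identical values. The log2 ratio of 3' to 5' signal for ACTB, a sign of RNA integrity, was 0.21 ± 0.02 in control, 0.22 ± 0.04 in si221 and 0.22 ± 0.005 in si222 (SD, n = 3). For GAPDH it was -0.18 ± 0.06, -0.16 ± 0.06 and -0.11 ± 0.08. The 18S ribosomal RNA control probe set read 11.03 ± 0.23 in si222 against 11.49 ± 0.10 in control and 11.45 ± 0.26 in si221 (log2, SD, n = 3).

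The clearest change with the miR-221 antagomir was a fall of interferon-induced genes. Of 36 tested members of the interferon response list, 33 were lower in si221 than in control over all genes tested, and 35 when adjusted over the list alone. The median log2 change was -0.81, and all 36 members had a negative value. OAS2, which makes the 2-5A messenger that activates RNase L, fell by 1.95 (SE 0.05, adjusted p = 5.2e-06), a 3.88-fold difference, with the same sign in all 3 of its probe sets. XAF1, a pro-apoptotic interferon-induced gene, fell by 1.76 (SE 0.05, adjusted p = 6.9e-06), and PSMB9, an immunoproteasome subunit, fell by 1.81 (SE 0.07, adjusted p = 2.39e-05). The antiviral genes TRIM22 and IFI44 fell by 1.42 and 1.39, and SAMD9L fell by 1.38 and RSAD2 was 2.83-fold lower. TAP1, the peptide transporter of antigen presentation, fell by 1.48 (SE 0.12, adjusted p = 0.000835). The list's shift had an adjusted p of 4.17e-66 with limma's camera, and 2.43e-05 with an estimated correlation. Between 27 and 31 of the members were called lower when any 1 of the 6 arrays was left out, an alternative added after the data were seen.

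**Figure D1:**
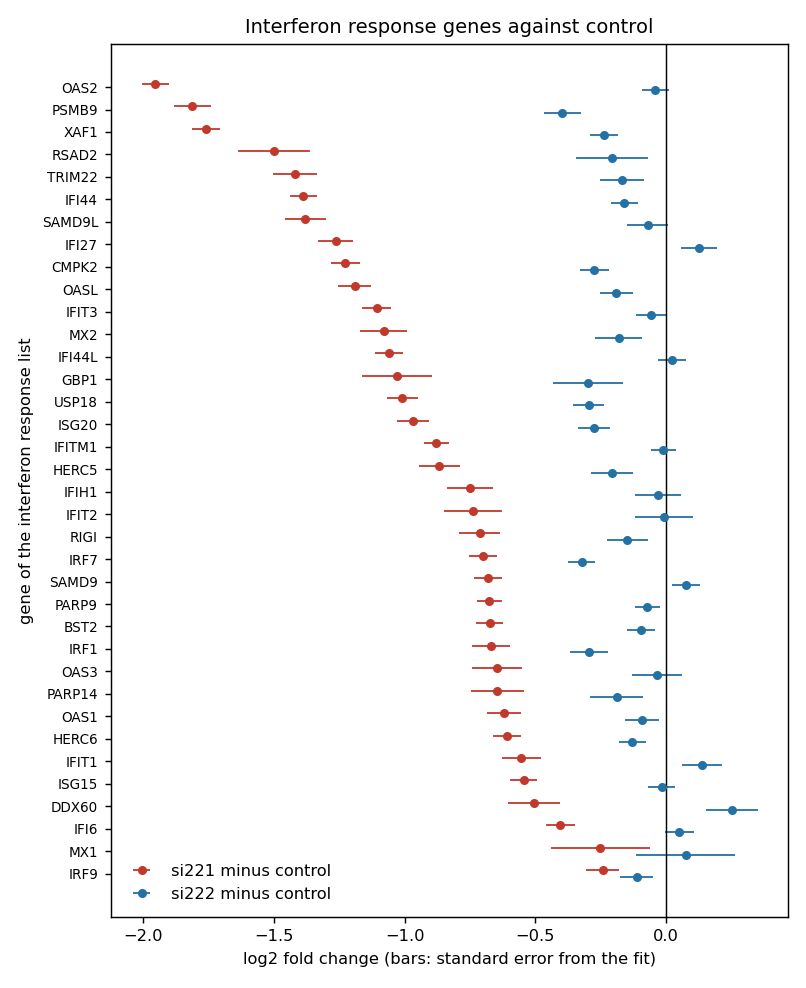
Log2 fold change against control of the 36 tested interferon response genes, in si221 (red) and si222 (blue), with bars for the standard error from the fit (n = 3 arrays per group). The si221 values have a median of -0.81 and are all below 0, and the si222 values have a median of -0.11.

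In total 194 of 13221 genes changed with the miR-221 antagomir, 51 higher and 143 lower, of which 5 rose and 25 fell at least 2-fold. The largest rise was that of HINT3, a nucleotide hydrolase of the histidine triad family, by 2.92 (SE 0.28, adjusted p = 0.00216). That is the probe set of HINT3 with the highest mean over all arrays, and its other 2 were 1.39 and 0.66 higher. In control the probe set that rose by 0.66 was the brighter, at 10.37 against 8.96. The choice by the mean over all arrays thus leaned on the signal in the treated groups. NKX6-3, a homeobox transcription factor, rose by 1.46 (SE 0.26, adjusted p = 0.0415), but it was dim, with a mean of 6.201 in control, and the call was lost when any of the 6 arrays was left out. In si222 NKX6-3 was 2.03 higher (SE 0.26) and not called. Other large rises were those of SVIL-AS1 (1.02), KCNAB3 (1.01), PSTPIP2 (1.00), ZNF682 (0.86), PARD6B (0.79) and PADI3 (0.77), the last a peptidylarginine deiminase whose call held in every alternative run. SVIL-AS1 is antisense to SVIL. With both treated groups averaged against control, these genes were 0.88, 0.68, 0.78, 0.71, 0.80 and 0.51 higher, in the order above. These averages contain the si221 arrays on which the genes were chosen, so they do not test whether the rises extend to si222. None of these genes was called in si222. With an array left out, the call was lost in 3 of 6 fits for SVIL-AS1, in 4 for KCNAB3 and in 5 for each of PSTPIP2, ZNF682 and PARD6B. For PARD6B, 1 of the 3 probe sets went the other way, and the mean over probe sets was 0.29 and not called. With that mean ZNF682 was at 0.58 and PSTPIP2 at 1.00, neither of them called, and PSTPIP2 also lost its call with quantile normalization, median centring or no pseudocount. At an unadjusted p under 0.05 there were 1969 genes against 661 expected by chance, and groups did not overlap for 21.9% of genes against 10% by chance. The count fell to between 88 and 100 without any of the 3 control arrays, si221 replicate 2 or si221 replicate 3, and rose to 414 with an intensity trend in the variance.

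Several other lists moved with si221. The NF-kappaB and inflammation list was lower (median -0.20, adjusted p = 4.13e-05, and 0.0228 with an estimated correlation), with 5 of 24 members lower and 6 when adjusted over the list alone. Among them the neutrophil chemokine CXCL8 fell by 0.95 (SE 0.10, adjusted p = 0.00298), the chemokine CCL5 fell by 0.90 (SE 0.13, adjusted p = 0.0148, lost in 4 of 6 fits with an array left out) and IRF1, also on the interferon list, fell by 0.67 (SE 0.07, adjusted p = 0.00426). In the unfolded protein response list (median -0.11, adjusted p = 9.25e-05, and 0.0228 with an estimated correlation), 2 of 30 members were lower, or 3 adjusted over the list alone: PPP1R15A, a phosphatase regulator that restores translation, by 0.65, and the stress transcription factor ATF3, by 0.59. The metallothioneins and oxidative stress list (median -0.10, adjusted p = 5.87e-05, and 0.0307 with an estimated correlation) had 4 of 25 members lower, or 6 adjusted over the list alone. These included the aldo-keto reductases AKR1C2, which fell by 0.84 (SE 0.06), AKR1C3, by 0.81 (SE 0.08), and AKR1C1, by 0.68 (SE 0.05). The AKR1C genes are close paralogs, and their probe sets can share signal. The hypoxia and glycolysis list was lower (median -0.10, adjusted p = 0.00273, and 0.0384 with an estimated correlation), with 1 of 32 members lower over all genes and over the list alone, PFKFB4, a regulator of glycolytic flux, by 0.62. Only 1 of the 2 PFKFB4 probe sets was lower, the value was -0.09 and not called with the mean over probe sets, and the call was lost in 5 of 6 fits with an array left out.

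Lists that moved upward with si221 had weaker support. Mesenchymal and stromal markers were higher (median 0.08, adjusted p = 0.0147), with 3 of 16 members higher, or 4 adjusted over the list alone, but the adjusted p was 0.167 with an estimated correlation, and 0.101 with a median of 0.05 without control replicate 1. SNAI2, a transcription factor that represses E-cadherin, rose by 0.70 (SE 0.08, adjusted p = 0.00702), and the collagen genes COL6A1 and COL5A1 rose by 0.56 and 0.33 but lost the call when any of the 6 arrays was left out. Basal breast markers were higher by the test (adjusted p = 0.0263, and 0.117 with an estimated correlation), although 6 of 12 members had a positive and 6 a negative value, and 3 passed, or 4 adjusted over the list alone. Those were the basal keratin KRT5, up 0.56 (SE 0.06, adjusted p = 0.00426), and the caveolae genes CAV1, up 0.51, and CAV2, up 0.37, the last with a call lost in 5 of 6 fits with an array left out and with the mean over probe sets. The list's median was 0.04, and -0.01 without control replicate 3. The G2/M list had a median of 0.06 with 0 of 39 members called (adjusted p = 0.0176, and 0.0696 with an estimated correlation). Among p53 targets, a list that was not called (median -0.02, adjusted p = 0.332), PMAIP1 fell by 0.65, GDF15 by 0.55 and GADD45A by 0.51, and 3 of 29 members passed, or 6 adjusted over the list alone. GADD45A lost its call when any of the 6 arrays was left out. GDF15 lost it in 4 of those 6 fits, and was at -0.32 and not called with the mean over probe sets. PMAIP1 also sits on the list of apoptosis regulators (median -0.06, adjusted p = 0.157), and was its single called member.

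The reported targets of the microRNAs did not shift as a list with si221 (median 0.02 over 30 tested genes, adjusted p = 0.461), and none was called over all genes or when adjusted over the list alone. By limma, 194 of all 13221 genes were called in this comparison, and 1969 had an unadjusted p under 0.05. CDKN1B, the cell cycle inhibitor p27, was 0.19 higher (SE 0.06, adjusted p = 0.222) and TRPS1 was 0.19 higher (SE 0.06, adjusted p = 0.217). ESR1, the gene of the estrogen receptor, was 0.14 higher (SE 0.14, adjusted p = 0.698), with that sign in 5 of its 6 passing probe sets, but it was -0.03 without si221 replicate 2. CDKN1C differed by -0.65 (SE 0.42, adjusted p = 0.522), TIMP3 by -0.11, FOXO3 by 0.03 and DICER1 by 0.09. CDKN1C was positive and DICER1 negative when probe sets were averaged. KIT lay below the filter on dim probe sets, and BBC3 and PTEN are not analysed here. The estrogen response list had a median of -0.01 (adjusted p = 0.536), with 1 of 41 members lower, STC2, by 0.29 (SE 0.05, adjusted p = 0.0458), or 4 adjusted over the list alone. The STC2 call was lost when any of the 6 arrays was left out.

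None of the remaining lists was called with si221 (adjusted p from 0.0538 to 0.797, and 0.954 for heat shock). Medians were 0.05 for DNA replication, 0.06 for TGF-beta, 0.06 for WNT, -0.03 for PI3K with AKT and FOXO, -0.01 for ERBB and MAPK, -0.07 for cholesterol synthesis and -0.04 for epithelial markers. They were -0.22 for leukocyte markers, 0.02 for ribosomal proteins, -0.05 for oxidative phosphorylation, -0.14 for histones, -0.01 for heat shock, 0.05 for microRNA machinery and -0.02 for drug handling. Within them, the leukocyte actin-bundling gene LCP1 fell by 0.30 and the RNA-editing enzyme gene ADAR fell by 0.29, and both calls were lost when any of the 6 arrays was left out.

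With the miR-222 antagomir 10 of 13221 genes changed, 2 higher and 8 lower, and 1615 had an unadjusted p under 0.05 against 661 expected by chance. Groups did not overlap for 20.6% of genes against 10% by chance. Of the called genes, 1 rose and 0 fell at least 2-fold with si222, against 5 and 25 with si221. Simulated 2-fold changes were recovered at 76% in si221 and 72% in si222. Those of 1.5-fold and 3-fold were recovered at 52% and 96% in both. The simulation planted 50 changed genes of each size in both comparisons, so its rates do not show why fewer genes were called with si222. A larger change could miss the call there. NKX6-3 was called at 1.46 in si221 and not at 2.03 in si222, with the same SE of 0.26. HINT3 rose by 2.49 (SE 0.28, adjusted p = 0.0396), with 0.89 and 0.45 for its other 2 probe sets, and its mean over probe sets was 1.28 and not called. FZD4, a WNT receptor, rose by 0.87 (SE 0.10, adjusted p = 0.0409). AKR1C3 fell by 0.85 (SE 0.08, adjusted p = 0.0235), AKR1C1 by 0.84 (SE 0.05, adjusted p = 0.00236) and AKR1C2 by 0.83 (SE 0.06, adjusted p = 0.01). The epidermal genes S100A7 and KRTDAP fell by 0.76 and 0.70. The stress-responsive genes GDF15, ATF3 and PMAIP1 fell by 0.62, 0.57 and 0.55. With the mean over probe sets only 2 of the 10 genes kept their call. GDF15 was at -0.26 there. AKR1C1 also lost its call, with an adjusted p of 0.0577, and it lost it with the replicate block (0.065). The count of 10 fell to 1 or 2 without any single one of the 6 arrays, where AKR1C1 was the only gene of the 10 to keep its call each time, and rose to 82 with an intensity trend in the variance.

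The interferon list had a median of -0.11 with si222, with 0 of 36 members called over all genes and 7 when adjusted over the list alone (adjusted p = 3.11e-05, and 0.0345 with an estimated correlation). Its members with the smallest p were PSMB9 at -0.40 and IRF7 at -0.32. The reported targets had a median of 0.11 over 30 genes (adjusted p = 0.0124), with an adjusted p of 0.0639 with an estimated correlation. None passed over all genes, and 3 passed when adjusted over the list alone: CDKN1B at 0.33 (SE 0.06, adjusted p over all genes 0.169, or 0.0329 with an intensity trend in the variance), RECK, an inhibitor of matrix metalloproteinases, at 0.46 (SE 0.09, adjusted p 0.172) and BCL2L11, a pro-apoptotic BH3 protein, at 0.20 (SE 0.05, adjusted p 0.233). ESR1 differed by 0.22 (SE 0.14), TRPS1 by 0.22 (SE 0.06), CDKN1C by -0.18 (SE 0.42), TIMP3 by -0.05, FOXO3 by -0.02 and DICER1 by 0.00, none of them called. Averaging probe sets turned the sign for CDKN1C, TIMP3, FOXO3 and DICER1. BCL2L11 is named after its value was seen.

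**Figure D2:**
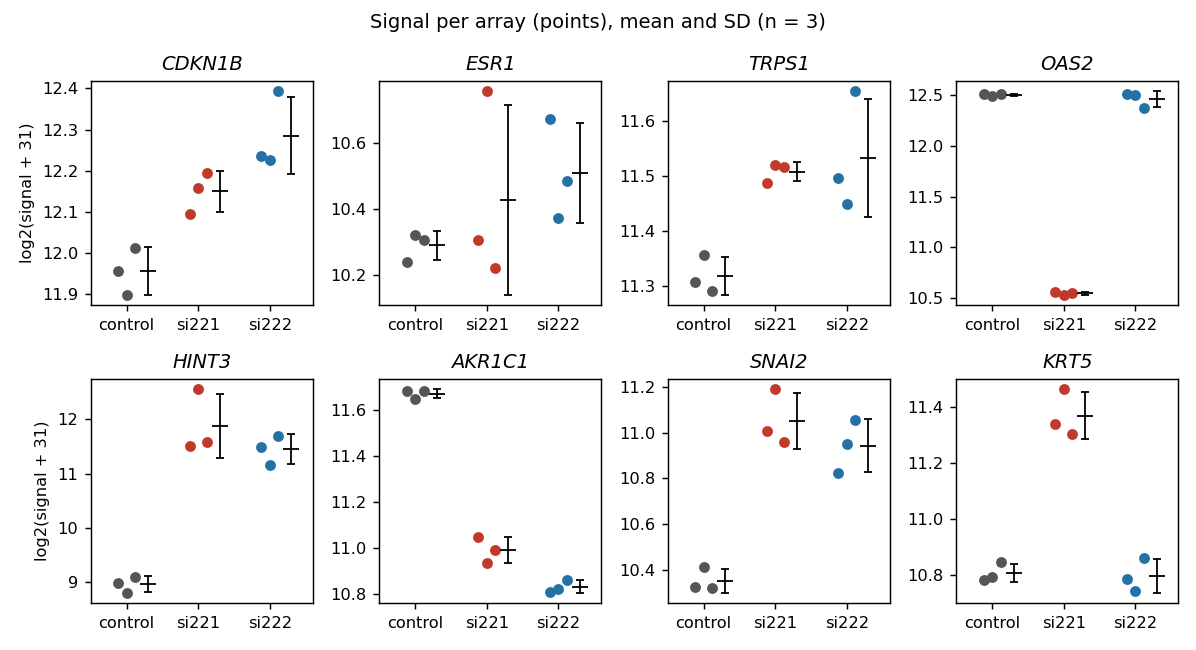
Log2(signal + 31) of 8 genes on each array (points, n = 3 per group) with the group mean and SD beside them; each panel has its own axis, which does not start at 0. CDKN1B, ESR1 and TRPS1 are reported targets, OAS2 is lower in si221 than in both other groups, and HINT3 is higher in both treated groups than in control.

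Other lists called with si222 lost the call with an estimated correlation. Mesenchymal markers had a median of 0.28 (adjusted p = 0.000147, and 0.0639 with an estimated correlation), with 0 of 16 members passing over all genes and 4 adjusted over the list alone. SNAI2 was 0.59 higher (SE 0.08, adjusted p = 0.0879). p53 targets had a median of -0.14 (adjusted p = 0.000445, and 0.0531 with an estimated correlation), with PMAIP1 and GDF15 lower, and 8 lower and 3 higher of 29 adjusted over the list alone. The oxidative stress list had a median of -0.10 (adjusted p = 0.001, and 0.0639 with an estimated correlation), with the 3 AKR1C genes lower. G2/M genes had a median of -0.05 (adjusted p = 0.0136, and 0.0639 with an estimated correlation), with 0 of 39 called. Ribosomal protein genes had a median of 0.09 (adjusted p = 0.000361, and 0.508 with an estimated correlation), with 0 of 33 called, and the median was -0.00 after quantile normalization. The 18S probe set was lower in the same group. The estrogen response list had a median of 0.00 (adjusted p = 0.712), with 0 of 41 members called. The lists not named here for si222 had adjusted p from 0.11 to 0.893.

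The direct comparison of the antagomirs called 78 genes, 69 higher and 9 lower in si222 than in si221. Of the 36 interferon genes, 31 were higher in si222, and 34 when adjusted over the list alone (median 0.73, adjusted p = 4.24e-74, and 1.72e-05 with an estimated correlation). OAS2 was 1.91 higher (SE 0.05, adjusted p = 6.14e-06), XAF1 1.52, PSMB9 1.41 and IFI27 1.39. In the other direction, KRT5 was lower in si222 by 0.57 and CLSTN2, a calsyntenin of the cell surface, by 0.62. S100A7 was lower by 0.47 and CBX5, which encodes heterochromatin protein 1 alpha, by 0.39, and both of these calls were lost when any of the 6 arrays was left out. G2/M genes differed by a median of -0.12 (adjusted p = 2.76e-08, and 0.00535 with an estimated correlation), with 36 of 39 members negative and 0 called. DNA replication genes differed by -0.12 (adjusted p = 1.52e-05, and 0.0368 with an estimated correlation), with 34 of 39 negative and 0 called. The count of 78 fell to between 44 and 51 without any 1 of the 3 si222 arrays.

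The 2 responses were correlated across genes, with r = 0.547 (jackknife SE 0.152) and a Spearman coefficient of 0.537, but genes are not independent replicates and both responses share the same controls. Simulated unchanged groups against shared controls gave a mean r of 0.497, with a range from 0.466 to 0.545, and a mean Spearman coefficient of 0.449, with a range from 0.424 to 0.470. The covariance was 0.0269 against 0.0175 simulated (0.0158 to 0.0195), a difference of 0.00944. Signs were the same for 70.6% of genes against 66.7% simulated (65.7% to 67.7%). All 4 values lay above the highest of the 100 simulations, r by little and by less than its jackknife SE. The simulations drew independent noise for each gene. Noise shared among the genes of an array could widen all 4 ranges, so lying above them does not settle a shared response. Both lists of calls shared 7 lower genes and 1 higher gene, where independent lists would share 0.0865 and 0.00772 and simulated unchanged groups shared 0 and 0.01 on average. The former leaves out the shared controls and the latter leaves out the effects, so neither gives the overlap due to chance here. Of the 194 genes called with si221, 169 had the same sign in si222 (87.1% against 89.3% simulated) and 69 differed between si222 and si221. The 3 controls cannot be split into sets of at least 2, so part of the excess may come from the shared controls.

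**Figure D3:**
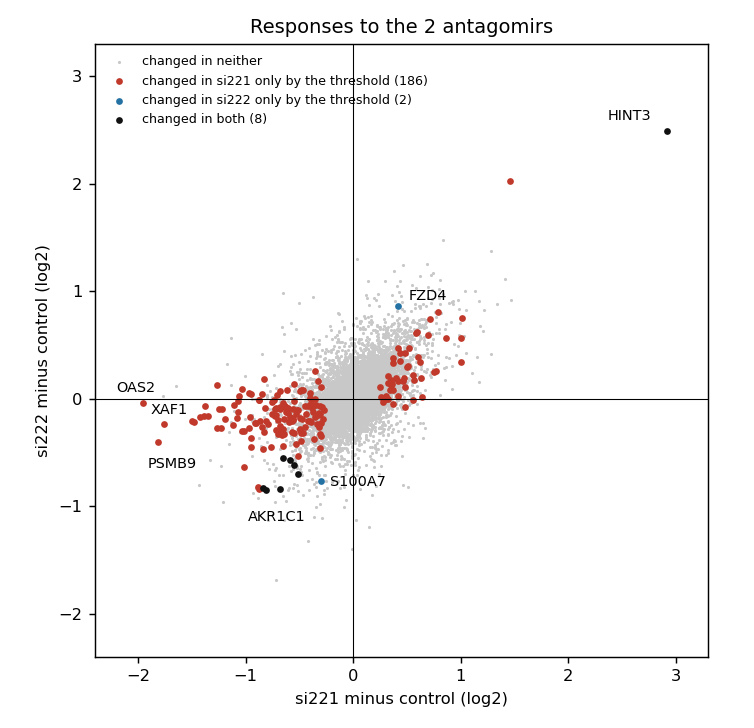
Log2 fold change of 13221 genes in si221 (x axis) and si222 (y axis), each against control, coloured by which comparison called the gene. There are 8 genes called in both, 186 called in si221 and not in si222, and 2 called in si222 and not in si221; the interferon genes OAS2, XAF1 and PSMB9 lie far to the left, at -0.04, -0.24 and -0.40 on the y axis, and HINT3 lies at the upper right.

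The moderated F test called 141 genes that differ among the 3 groups. This count fell to between 72 and 76 without control replicate 1, 2 or 3 or si221 replicate 3, to 93 without si221 replicate 1, to 84 without si221 replicate 2 and to 91 without si222 replicate 2.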

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

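Tests of array scaling, of transfection in common, of probe sets and of NRF2 targets were chosen after the results were seen, while the counts over other splits of the arrays were set beforehand. The lists and genes of the next paragraph differed between the antagomirs in the direct test of si222 against si221. The probe sets of the paragraph after it entered no gene comparison. HINT3 and the AKR1C genes are discussed further below because they moved in both treated groups.

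Among gene lists, the difference between si222 and si221 was a median of 0.73 for the interferon response, 0.23 for leukocyte markers, 0.21 for NF-kappaB and inflammation, 0.18 for histones, 0.0855 for reported microRNA targets, 0.0843 for the unfolded protein response, 0.082 for cholesterol synthesis, 0.0797 for hypoxia and glycolysis, 0.0671 for ribosomal proteins, 0.061 for heat shock and 0.0602 for oxidative phosphorylation. It was -0.12 for G2/M, -0.12 for DNA replication and -0.0473 for p53 targets. With an estimated correlation, 6 of these 14 lists kept a call. Those that lost it were leukocyte markers (adjusted p = 0.0575), histones (0.0575), reported targets (0.0955), p53 targets (0.0834), cholesterol synthesis (0.0834), heat shock (0.21), oxidative phosphorylation (0.362) and ribosomal proteins (0.565). Leukocyte markers had an adjusted p of 0.8 with no filter, and the median for ribosomal proteins was -0.02 after quantile normalization. Among genes, the difference was 1.91 for OAS2, 1.63 for VRTN, 1.52 for XAF1, 1.41 for PSMB9, 1.39 for IFI27, 1.31 for SAMD9L, 1.29 for RSAD2 and 1.27 for TAP1. It was -0.83 for SRGAP2, -0.62 for CLSTN2, -0.57 for KRT5, -0.56 for ATP8A1, -0.47 for S100A7, -0.41 for AHNAK, -0.39 for CBX5 and -0.36 for C2orf76. When any of the 6 arrays was left out, S100A7, AHNAK, CBX5 and C2orf76 lost their calls, and VRTN, SRGAP2 and ATP8A1 lost theirs in 5 of 6 such fits. C2orf76 and ATP8A1 also lost them with quantile normalization, median centring or an intensity trend.

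Of 6484 probe sets without a single gene name that passed the filter, 24 were called in si221 against control, 11 higher and 13 lower. In si222 against si221, 20 were called. In si222 against control limma called 0 of them, in a fit of every probe set that called 2 in all. In the fit of named genes 10 were called, and 1615 had an unadjusted p under 0.05.

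The fall of interferon genes in si221 was weighed against technical explanations. Array scaling is argued against by the median of the list, which was -0.82 under quantile normalization, the higher of the 2 other scalings. A transfection effect of the same size in both treated groups would leave no difference between them, but the list differed by 0.73. This value does not address an effect of unequal size in the groups, and the treatment of the controls is not settled. A culture or handling day shared by the si221 arrays cannot be told apart from the antagomir, since no label gives batches and the widest spread within a group was 0.053. Inhibition of miR-221, the factor the design names, stays open as well, and the microRNA was not measured.

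HINT3 was higher in both treated groups. The other 2 probe sets also rose, with 0.45 as the smallest change, which argues against cross-hybridisation of 1 probe set as the whole cause. In a fit of every probe set, neither was called in si222 (adjusted p = 0.255 and 0.341), nor was the probe set used above (0.108). In si221, 1 of them was called (0.0393) and the other was not (0.0945). Their rises were smaller than the 2.92 and 2.49 of the probe set used, so part of that size may be particular to it. An effect of transfection or of any oligonucleotide cannot be told apart from inhibition of the microRNAs, because the treatment of the controls is not settled and the groups differed by -0.43, which was not called. Leaving out any of the 6 arrays of the si222 comparison ended the call there, while the call in si221 held in every alternative run.

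AKR1C1, AKR1C2 and AKR1C3 were lower in both treated groups. Signal shared between these paralogs stays open, since AKR1C3 fell by at least 1.02 times the mean fall of the other 2 genes and its probes were not searched for unique sequence. A lower output of NRF2, the regulator of oxidative stress genes, is a candidate explanation that also stays open. The other 14 NRF2 targets tested had medians of -0.10 in si221 and -0.10 in si222. With camera the adjusted p was 0.00106 in si221 and 0.0185 in si222. With an estimated correlation it was 0.0121 in si221 and 0.0732 in si222, so the list passed in si221 and not in si222. These shifts are far smaller than those of the AKR1C genes, and inhibition of the microRNAs was not tested as a cause.

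Other splits of the same arrays were counted for each comparison. For si221 against control the real split gave 194 genes and the highest other split 1, for si222 against control 10 and 0, and for si222 against si221 78 and 0. In each case 1 of 10 splits, the real one, reached the count, and 10 splits are too few for a share under 0.05, so chance cannot be told apart by this test. For the 3 groups together, 1 of 100 splits, the real one, reached 141 genes, and the highest other split gave 67. The arrays thus differ by group more than under relabelling. Since the arrays of a group may come from 1 culture, chance differences between cultures are not excluded.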

How the results depend on the processing

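Alternatives were planned except the count of interferon genes lower in si221, added after the data were seen, which ran from 27 to 35 against 33. No called gene that the text follows through the alternatives changed direction in any of them. Array weights kept 66 of 66 such calls, the replicate block 30, no filter 37, and leave-one-out fits 212 of 396. Counts depended on the variance model, whose prior of 1.86 degrees of freedom is small, and the cause was not tested further.

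Genes changed in si221 (194) numbered 98 with no filter, 328 with the top 40% filter, 414 with an intensity trend, 95 with only the 2 groups, 85 with the replicate block and 88 to 154 with an array left out. In si222 (10) they numbered 1, 17, 82, 4 and 0 under these settings, 2 with every probe set, 2 with the mean over probe sets, and 1 to 2 with an array left out. Under the block, limma called 0 in si222, where 1615 genes had an unadjusted p under 0.05 without it. In si222 against si221 (78) they numbered 171 with the trend, 37 with only the 2 groups, 45 with the block and 44 to 59 with an array left out. The genes that differ among the 3 groups (141) numbered 74 with no filter, 238 with the top 40%, 400 with the trend, 59 with the block and 72 to 106 with an array left out. Same-numbered arrays did not deviate together, with correlations from -0.017 to 0.03, so the block had no pairing to remove.

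List calls numbered 29, 12 with an estimated correlation and 71 with fry's mixed test, which asks whether genes change either way. The list interferon response, si221 against control, had medians that ran from -0.87 to -0.78, with adjusted p from 3.25e-75 to 2.43e-05. The target list in si222 (median 0.11) had an adjusted p of 0.0639 with an estimated correlation. In si222 against si221 the target list lost its call in several settings. Its median log2 difference there was 0.0813 with no filter (adjusted p = 0.0641), 0.0564 with the top 40% (0.0919), 0.0883 with quantile normalization (0.055), 0.0834 with array weights (0.072) and 0.0855 with an estimated correlation (0.0955). With any 1 array other than si221 replicate 3 left out, the median lay between 0.049 and 0.0986, with adjusted p from 0.058 to 0.172. The ribosomal median was -0.00375 in si222 and -0.0189 against si221 with quantile normalization. The response correlation ran from 0.488 to 0.620.

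CDKN1B in si222 was called only with the intensity trend, where its adjusted p was 0.0329, against 0.0835 to 0.36 in the others. Uncalled targets changed sign with the mean over probe sets: CDKN1C to 0.12 and 0.32 in si221 and si222, DICER1 to -0.0927 and -0.0984, TIMP3 to 0.0734 and FOXO3 to 0.10 in si222. With an array left out, ESR1 ran from -0.0263 to 0.242 in si221, FOXO3 from -0.0494 to 0.018 in si222 and DICER1 from -0.033 to 0.048 in si222.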

Other observations

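The tests in this part were all chosen after the results were seen. A list of antigen presentation genes, written once class I genes had been noticed among the calls, had 12 of 20 tested members lower in si221, with a median of -0.62. Besides TAP1 and PSMB9, HLA-F fell by 1.07 (SE 0.06), HLA-G by 0.84 (SE 0.12), HLA-B by 0.83 (SE 0.05), HLA-E by 0.72 (SE 0.05) and HLA-C by 0.61 (SE 0.05). The class I genes have similar sequences, and their probe sets can share signal. TAP2, the partner of TAP1, fell by 0.63, and NLRC5, the transactivator of class I genes, fell by 1.27 (SE 0.24, adjusted p = 0.0484). B2M was at -0.23 (adjusted p = 0.0814) and the chaperones CALR and CANX at -0.12 and 0.02, none of them called. In si222 the list had a median of -0.04 with 0 of 20 members called by limma. Only 10 of all 13221 genes were called in that comparison, and 1615 had an unadjusted p under 0.05, so 0 of 20 says little. In the direct comparison 9 members were higher in si222 than in si221. Since the list was written for the pattern, its count is a description and not independent evidence.

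A list of immediate early and stress genes, also written after the data were seen, had 7 of 38 members lower in si221: ATF3, ARC, RASD1, GEM, PPP1R15A, GADD45A and GADD45B. RASD1 was at -0.88 in si221 and -0.84 in si222, and ARC at -0.88 and -0.82, though neither was called in si222. Over all 38 members the medians were -0.12 in si221 and -0.09 in si222, with adjusted p of 0.0025 and 0.00815 with an estimated correlation. Since the list was written after these genes had been seen to fall, those values describe the pattern and do not test it. The 31 members not called in either group had a median of -0.10 in si221, with 22 negative and 9 positive values. In si222 their median was -0.02, with 16 negative and 15 positive. Their camera adjusted p with an estimated correlation was 0.0121 in si221 and 0.0798 in si222. Leaving out the called genes takes away those that fell most. Whether the whole set shifts stays open.

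The hypothesis that reported targets rise under the mean of both antagomirs was tested by averaging both treated groups against control. This contrast called 118 genes, 33 higher and 85 lower. A call here can come from 1 group alone: 26 of 36 interferon genes were called lower, against 33 in si221 and 0 in si222. The target list had a median of 0.05 and an adjusted p of 0.0902, or 0.154 with an estimated correlation, so the hypothesis was not borne out at the threshold. CDKN1B was 0.26 higher (SE 0.06, adjusted p = 0.0908), RECK 0.34 (SE 0.08, adjusted p = 0.125) and TRPS1 0.20 (SE 0.05, adjusted p = 0.156). Genes called higher in this contrast included SNAI2 at 0.65, IGFBP5, a secreted binder of insulin-like growth factors, at 0.61, and HMGA2, a chromatin protein, at 0.40.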
